A study of Homo sapiens with 132 samples.

How the data were processed

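RNA from 132 formalin-fixed, paraffin-embedded hepatocellular carcinomas, dissected from livers removed at transplantation, had been hybridised to Illumina whole-genome bead arrays, a single array per tumour. Per the labels, RNA was isolated with the miRNeasy FFPE kit and labelled with biotin. Formalin fixation fragments RNA, and the share of an array's signal that comes from specific hybridisation varies with the quality of the sample. Tumours were grouped by the collecting centre named in their labels, 99 from centre A and 33 from centre B. The labels used here gave no outcome, stage or serum marker, so none was analysed. Each array was treated as a separate tumour, because nothing in the labels says that a patient gave more than a single tumour.

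The authors deposited a table of probe intensity on the linear scale, exported with GenomeStudio 3, per the submitters' processing notes. Its values had not been brought to a common scale, since the median intensity of an array lay between 58.8 and 1433, with a middle value of 213. The table carries no detection p-values and no control probes. A second deposited table holds the authors' processed intensity values for the same 132 arrays on a linear scale, with column medians between 201.9 and 203.7. The ranks of each of its columns were closest to those of the same array in the first table for 132 of 132 arrays. Its background correction and normalization are not given in the sources used here, and it served as an alternative on the log2 scale. Both tables hold 29358 probes. The probe annotation gave 27969 probes a single gene symbol, 0 probes several and 1389 probes none, and the Entrez identifiers of 27800 probes matched the gene table, with 0 symbols updated.

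The main values were made from the unnormalized intensities with limma 3.58.1 in R 4.3.3. The background was corrected with normexp and an offset of 50, arrays were quantile normalized, and values were taken to log2. The planned normalization, neqc with detection p-values, needs columns that the table does not carry. Detection was therefore called against the 2936 probes (10% of all) of lowest mean rank: a probe's detection p on an array was the share of these probes with at least its signal. Probes with a detection p under 0.01 on at least 10% of arrays, which is 14, were kept. From all steps, 116 probes of Y-linked and X-inactivation genes were left out. The filter kept 24271 probes, of which 23139 had a gene name, and each gene was represented by its kept probe of highest mean level. This gave 16747 genes, 4506 of them with more than 1 kept probe. No level was set against another probe's level. Between 11621 and 21626 probes were detected per array, with a middle value of 18650. No pair of arrays held identical values, and the highest rank correlation between arrays was 0.979. The number of arrays limits the precision.

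A quality measure was added after the data were seen. It is the mean normalized log2 level of 487 probes for olfactory receptors and keratin-associated proteins, gene families that liver tissue has no known use for, and is called the nonspecific signal index. Every comparison was also fitted with this index as a covariate and without the 33 arrays of highest index. The labels name no slide or array batch, so a batch cannot be separated from the centre. After the data were seen, the order in which the tumours of each centre are listed was searched for the break that best parts the index, and compared with 1000 random orders.

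Centres were compared with limma's lmFit and eBayes, centre B minus centre A. Genes associated with KRT19, AFP or GLUL, called anchor genes, were found with the same functions by regressing each gene on the anchor gene's log2 level with the centre as a covariate, so that tumours were never split by an anchor gene. A slope is in log2 per log2 unit of the anchor. All tests were two-sided, and adjusted p-values are those of limma after Benjamini-Hochberg adjustment, called at 0.05. Lists of genes were tested with camera at its preset correlation of 0.01, with an estimated correlation, and, for the centres, with fry. Fry asks whether the genes of a list move on balance in a single direction, and its mixed test whether they change in either direction. Correlations across tumours have Pearson's r and Spearman's rho with permutation p-values from 100000 resamples in python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The smallest p-value these permutations can give is 1e-05. Differences between the centres' correlations were tested by 10000 permutations of the centre labels. A list enters a correlation as its score, the mean over its genes of values centred and scaled per gene.

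The groups, the fits, the 24 gene lists, the 24 pairs and the rule for naming genes were fixed before the data were examined. The rule took the 12 genes higher and the 12 lower with the greatest log2 difference between the centres among those past the threshold. For each anchor gene it took the 10 genes with the strongest positive and the 10 with the strongest negative association, and for each list up to 4 members with the smallest p. It also took the 15 genes with the greatest SD among genes detected in at least 50% of the tumours, and the genes of the fixed pairs. Under this rule 10 and 10 genes were also taken from each anchor fit with the index, and 12 and 12 from the centre fit with the index, which was chosen after the data were seen. Lists of cell types cover hepatocyte function, biliary and progenitor cells, stellate cells and fibroblasts, endothelial cells, T and NK cells, B and plasma cells, macrophages, neutrophils and red blood cells. Lists of programmes cover oncofetal genes, WNT and beta-catenin targets, proliferation, interferon response, antigen presentation, hypoxia and glycolysis, and the acute phase. The others cover complement and coagulation, lipid and cholesterol synthesis, bile acid and xenobiotic transport, NRF2 targets, metallothioneins, early response and heat shock, ribosomal proteins, and the respiratory chain. Of their 391 members, 358 were tested, and the others were not analysed here.

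Alternatives fixed in advance were the authors' values, no background correction, no filter or a filter at 50% of the arrays (66), and the mean of all kept probes of a gene. The tumours were also compared after leaving out 5 tumours whose title prefix was that of the other centre or regrouping by that prefix. Further fits had the number of detected probes as a covariate, array weights, or the hepatocyte score as a covariate, or left out 5 arrays with few detected probes (more than 1.5 interquartile ranges below the lower quartile, all from centre A). A log2 difference of at least 1 was asked for as well, and anchor genes were fitted within each centre, without the centre, or without the 2 tumours at the extremes of an anchor gene. The alternatives chosen after the data were seen were those with the index, neqc with the 2936 lowest probes as controls, and other probes of an anchor gene. The fits were tested on simulated data at the real sample sizes, over 16747 genes. A difference of 0.5 log2 between the centres was recovered for 48% of 100 changed genes and a difference of 1 log2 for 94%, with 5 false calls. For genes associated with KRT19, a slope of 0.2 was recovered for 90% of 100 genes and a slope of 0.4 for 100%, with 7 false calls. The simulated genes varied independently of each other, while in the real data the first principal component held 41.8% of the variance. These rates therefore do not say how many false calls the real data give.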

Results

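Gene expression was measured in hepatocellular carcinomas beyond the Milan criteria, the limits of tumour size and number commonly used for liver transplantation. The tumours came from explanted livers, 99 from centre A and 33 from centre B, and the median of detected probes was 18505 per array in centre A and 19023 in centre B. The design allows a comparison between the collecting centres and, across tumours, of each gene with markers of known classes of this cancer.

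CYP3A4, the main drug-metabolising cytochrome P450 of the adult liver, had an SD of 2.01 (n = 99 and 33), with 90% of the tumours between 6.98 and 12.89. Markers of tumour classes spread widely. AFP, the fetal serum protein, was detected in 96.97% of tumours with an SD of 1.57. KRT19, a cytokeratin of bile duct cells, was detected in 81.1% with an SD of 1.84, and GLUL, the glutamine synthetase of perivenous hepatocytes, in 99.2% with an SD of 1.25. Of the 358 listed genes, 346 were detected in at least 50% of the tumours, and 327 were at the stricter detection p of 0.01. Among all 16747 genes, 13422 had a probe detected at that stricter p on at least 50% of the arrays. All of them had already passed the filter on detection. Detection means a signal above that of the lowest probes, which nonspecific signal can also give. The olfactory receptor gene OR10G8 was detected in 56.1% of tumours. The median SD was 0.86 over the listed genes and 0.70 over all genes. By list the median SD was highest for oncofetal genes (1.36) and WNT and beta-catenin targets (1.31), where DLK1, an imprinted gene of fetal liver, reached 2.25 and REG3A, a secreted lectin, 2.64. Of these genes CYP3A4 and REG3A were chosen after their values were seen. The lowest medians were those of ribosomal proteins (0.58) and of hypoxia and glycolysis (0.61).

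Among all genes detected in at least 50% of the tumours, the widest spread belonged to genes without a known role in liver. REXO1L1P had an SD of 3.39, the cancer-testis genes GAGE4 and GAGE12J 3.17 and 3.07, and REXO1L6P 2.90. The olfactory receptor gene OR10G8 had an SD of 2.89, and the others among the 15 with the widest spread were PRAMEF18, POU4F3, GAGE12C, OTOL1, NPTX1, KCNH5, CSH2, CCDC190, TAFA4 and USP17L2. Without the 33 arrays of highest nonspecific signal index the SD of OR10G8 was 2.15 and that of GAGE4 2.70.

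The largest component of variation went along with the signal of gene families silent in liver. The nonspecific signal index lay between 6.35 and 9.33, and the first principal component of all genes, with 41.8% of the variance, had a correlation of 0.987 with it. Over the 16747 genes, 3737 had a correlation above 0.5 with the index and 5131 below -0.5, and the index held a median of 27.7% of a gene's variance. Several lists had lower scores on arrays of high index: that of hypoxia and glycolysis had r = -0.737 with the index, that of the respiratory chain r = -0.712 and that of ribosomal proteins r = -0.710. Early response and heat shock followed at r = -0.581, and bile acid and xenobiotic transport at r = -0.577. Cell type lists moved less with it, from r = -0.338 for hepatocyte function through r = -0.313 for stellate cells and fibroblasts and r = -0.138 for T and NK cells to r = 0.251 for red blood cells. The index averaged 7.11 ± 0.78 (SD, n = 99) in centre A and 7.60 ± 0.86 (SD, n = 33) in centre B, and the 33 arrays with the highest index held 16.2% of the tumours of centre A and 51.5% of centre B. Centre B fell into a pair of parts by the order in which its tumours are listed. The 13 listed first had an index of 6.70 ± 0.14 (SD) and the 20 listed later 8.18 ± 0.58 (SD), and this break held 72.3% of the variance of the index, against at most 41.3% in 1000 random orders. Between these parts of centre B 10711 of 16747 genes differed, and 42 did with the index as a covariate. The break was picked by the index, and the parts had r = 0.850 with it, so these counts follow it in part. A fit that holds both can hardly tell the parts from the index. In centre A the best break held 2.09% of the variance of the index.

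**Figure D1:**
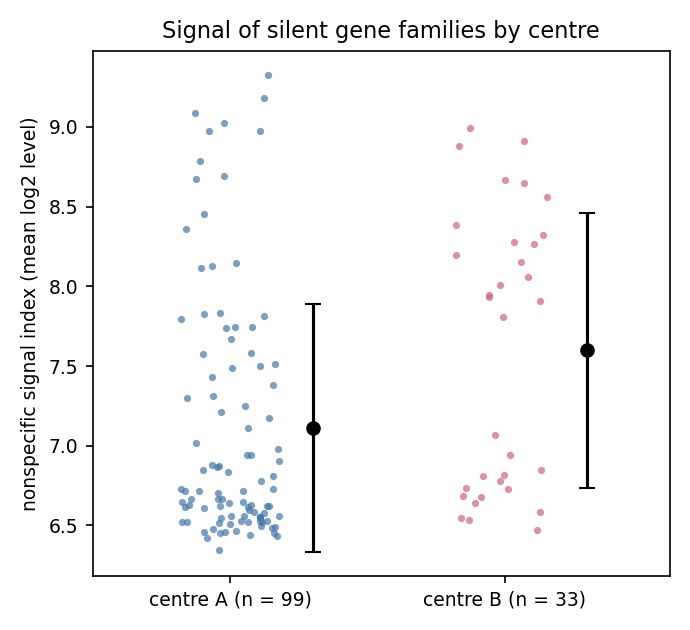
Nonspecific signal index per tumour (mean normalized log2 level of 487 probes for olfactory receptors and keratin-associated proteins) by collecting centre, with the mean and SD of each centre. Centre B averaged 7.60 and centre A 7.11, and arrays of both centres spread from near 6.35 upward.

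GDF15, a stress-induced cytokine, was 2.25-fold lower in centre B than in centre A (log2 difference -1.17, SE 0.21, limma adjusted p = 0.000186), and IER5L, an immediate early gene, 2.18-fold (-1.13, SE 0.17). CCL2, the chemokine that attracts monocytes, was lower by 2.11-fold (-1.08, SE 0.23), and NFKBIZ, an inhibitor protein of the NF-kB family, 2.09-fold (-1.06, SE 0.21; n = 99 and 33 throughout). All 4 stayed lower with the index as a covariate, at differences of -0.79, -0.96, -0.98 and -0.84. Centre B was higher in FKBP5, a co-chaperone of the glucocorticoid receptor, by 2.07-fold (log2 difference 1.05, SE 0.20), and in TAT, tyrosine aminotransferase, by 2.04-fold (1.03, SE 0.27). It was also higher in CYP4A11, a fatty acid hydroxylase, by 2.70-fold (1.43, SE 0.28), and in PGAM4, a phosphoglycerate mutase gene, by 0.97 log2 (SE 0.15). With the index in the fit these differences were 1.22, 1.13, 1.64 and 1.04, and all passed. FKBP5, TAT, CYP4A11 and PGAM4 were named by that fit, which was chosen after the data were seen. Without the 33 arrays of highest index GDF15, CCL2 and TAT did not pass (limma adjusted p = 0.163, 0.115 and 0.137), while the other genes of this paragraph did.

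By limma, 2796 of 16747 genes differed between the centres, 1355 higher and 1441 lower in centre B. With the index as a covariate 1471 did, 990 higher and 481 lower, and 497 genes were called in both fits, all in the same direction. The 12 genes with the greatest positive differences were mainly genes not known to be active in liver: DRD3, a dopamine receptor (log2 difference 2.14, SE 0.56), REXO1L1P, and the olfactory receptor genes OR2G2, OR51S1, OR11H12 and OR10G8. With them were the cancer-testis genes GAGE4, GAGE12J and MAGEA10, DSCR8, the potassium channel gene KCNH5, and GABRB1, a GABA receptor subunit. The index is made from olfactory receptor genes among others. Outside that family correlations with it lay between 0.784 (GAGE12J) and 0.928 (GABRB1), and with the index in the fit only GABRB1 (0.60, adjusted p = 0.00632) and the olfactory receptor gene OR2G2 (0.58, adjusted p = 0.0288) still passed. Other probes of DRD3 gave differences of 0.03 and 0.80 in place of 2.14, those of DSCR8 0.44 and 0.00422 in place of 1.81, that of KCNH5 1.14 in place of 1.78, and that of MAGEA10 0.96 in place of 1.73. On the lower side the rule also named G0S2, GEM, NRF1, SNORD2, MIR2276, CD83, KRT23 and LTB, between -1.05 and -0.95. With the index all of these but NRF1 (adjusted p = 0.0606) and LTB (adjusted p = 0.0890) still passed. The other CD83 probe gave -0.19 in place of -0.96, the other LTB probe -0.49 in place of -0.95, and the other NRF1 probes -0.32 and -0.22.

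With the index as a covariate, CYP4A11, FKBP5 and TAT had the greatest positive differences. After them came GNMT, a glycine methyltransferase, at 1.11 (SE 0.34), GSTA2, a glutathione transferase, at 1.11 (SE 0.34), METRN at 1.09 (SE 0.28), and PGAM4. Then followed SAA4, a constitutive serum amyloid, at 0.98 (SE 0.26), DECR2, a peroxisomal reductase of fatty acid oxidation, at 0.97 (SE 0.25), and TSC22D3, a glucocorticoid-induced gene, at 0.97 (SE 0.21), with FTH1P12 and LRRC25 at the same size. On the lower side were ELF3, an epithelial transcription factor, at -0.97 (SE 0.16), and SOX5 at -0.96 (SE 0.15). So were NRARP, a Notch target, at -0.87 (SE 0.23), SLC2A3, a glucose transporter, at -0.80 (SE 0.21), and TSSC2, MIR221 and ACAN. Of these, GNMT, GSTA2, METRN, DECR2, TSSC2, MIR221 and ACAN passed only with the index in the fit. Without it ACAN had a difference of 0.11 and TSSC2 of -0.07, against -0.81 and -0.86 with it. VEGFA, the endothelial growth factor, was chosen after its value was seen and was also lower with the index (-0.79, SE 0.13, adjusted p = 1.0e-05) and not without it (-0.43, adjusted p = 0.0603).

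No list passed between the centres: camera called 0 of 24 lists at its preset correlation, 0 with an estimated correlation, and fry 0, while 5674 single genes had an unadjusted p under 0.05. Within the lists, 5 of 16 biliary and progenitor genes were lower in centre B (5 adjusted over the list alone; camera adjusted p = 0.138), among them SOX9, a transcription factor of bile duct cells (-0.83, SE 0.21), and KRT23 (-0.95, SE 0.25). Stellate cells and fibroblasts had 4 of 19 lower (6 adjusted over the list alone), led by the collagen genes COL3A1 (-0.88, SE 0.24) and COL1A2 (-0.66, SE 0.22). Endothelial cells had 4 of 16 lower and 1 higher (5 and 1 over the list alone), with CDH5 (-0.57, SE 0.15) and PECAM1 (-0.51, SE 0.14). The index moved with these groups (r = -0.221, -0.313 and -0.332 for their scores), and with it in the fit 2, 0 and 0 of their genes were lower. Without the 33 arrays of highest index camera called all 3 lower, with 0 genes of each past the threshold (adjusted p = 0.0239, 0.0229 and 0.0460, adjusted p = 0.844 for each with an estimated correlation). With the index, camera called hepatocyte function (4 of 26 higher; adjusted p = 9.6e-05), complement and coagulation (2 of 19 higher; adjusted p = 0.00619) and the respiratory chain (5 of 15 higher; adjusted p = 1.3e-05) higher in centre B. It called biliary and progenitor cells lower (adjusted p = 0.0403). For the respiratory chain without the index, the median difference was -0.02 while the mean was 0.04 and camera pointed up. None of the 4 held with an estimated correlation (adjusted p = 0.981, 0.981, 0.285 and 0.981 with an estimated correlation). Early response and heat shock had 2 of 15 lower and 1 higher (camera adjusted p = 0.142, and 0.560 with the index). Without the 33 arrays of highest index camera called it and red blood cells lower (adjusted p = 0.0460 and 0.0472). It then called hepatocyte function, the respiratory chain, bile acid and xenobiotic transport, and complement and coagulation higher (adjusted p = 0.0186, 0.0229, 0.0392 and 0.0482). None of these held (adjusted p = 0.844 for each with an estimated correlation). Without the 33 arrays of highest index, 91 genes differed between the centres.

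KRT19 marks bile duct and progenitor cells, and its presence in hepatocellular carcinoma defines a class with progenitor features. CLIC6, a chloride channel protein, had a slope of 0.39 on KRT19 (SE 0.05, limma adjusted p = 4.7e-10, n = 99 and 33), and PROM1, the progenitor marker CD133, 0.49 (SE 0.07). SCTR, the secretin receptor of bile ducts, had 0.40 (SE 0.05), and KRT80 0.20 (SE 0.03). On the opposite side were RETSAT, a retinol saturase, at -0.19 (SE 0.03), and ABCB4, the phospholipid exporter of the bile canaliculus, at -0.32 (SE 0.05). So were F13B, a subunit of coagulation factor XIII, at -0.33 (SE 0.05), and QDPR, which recycles tetrahydrobiopterin, at -0.23 (SE 0.03). The index had r = 0.145 with KRT19, and with it in the fit the slopes of CLIC6 and ABCB4 were 0.39 and -0.28.

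By limma, 3751 genes were associated with KRT19, 1442 positively and 2309 negatively, and 2554 were with the index, 2270 of them in both. The other positive genes named by the rule were ANXA8L2, TRPV6, CHST4, VTCN1, ITGA3 and SLC5A1, with slopes between 0.23 and 0.46, and the other negative ones RTP3, PIPOX, PCBD1, PCK2, KLF15 and SLC10A5, between -0.32 and -0.21. Across tumours CLIC6 and KRT19 had r = 0.598 and rho = 0.593 (permutation p = 1e-05 for each, the smallest the permutations can give; adjusted p = 1.2e-05 over a family of 120), 0.598 without the 2 tumours at the extremes of KRT19, 0.628 in centre A and 0.453 in centre B. The family of 120 holds the genes named for the anchor genes, some of them under both fits. Such genes were picked by their slopes in these same tumours, so their permutation p-values, here and below, are no separate test. TRPV6, a calcium channel, had r = 0.534 and rho = 0.529 over all tumours (permutation p = 1e-05 for each), 0.512 without the 2 at the extremes, 0.609 in centre A and 0.150 in centre B, and no gene's slope differed between the centres in limma's interaction test (0 genes, against 348 at an unadjusted p under 0.05).

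In the list of biliary and progenitor cells 7 of 15 genes were higher with KRT19 and 0 lower (7 adjusted over the list alone; camera adjusted p = 5.6e-06, adjusted p = 0.0616 with an estimated correlation), among them MUC1, a mucin (0.25, SE 0.05), and the surface marker EPCAM (0.25, SE 0.05). With the index 9 were, and the call then held (adjusted p = 0.00567 with an estimated correlation). Bile acid and xenobiotic transport was lower in 9 of 13 (10 over the list alone; adjusted p = 0.0639 with an estimated correlation, 0.0105 with the index), with BAAT, which conjugates bile acids, at -0.30 (SE 0.05). Complement and coagulation was lower in 18 of 19 (18 over the list alone; adjusted p = 0.0958 with an estimated correlation, 0.0476 with the index), including SERPINC1, antithrombin, at -0.22 (SE 0.04). Hepatocyte function fell in 19 of 26 genes (25 over the list alone; adjusted p = 0.183 with an estimated correlation, 0.126 with the index), with APOH at -0.30 (SE 0.06) and CPS1, the first enzyme of the urea cycle, at -0.29 (SE 0.07). Of the 11 lists that camera called with KRT19, none held with an estimated correlation without the index, and the biliary, bile acid and complement lists did with it.

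Stellate cells and fibroblasts rose with KRT19 in 7 of 19 genes (8 over the list alone; adjusted p = 0.379 with an estimated correlation), led by FBLN1, fibulin 1, at 0.30 (SE 0.06) and DCN, decorin, at 0.13 (SE 0.03). B and plasma cells rose in 3 of 11 (5 over the list alone; adjusted p = 0.338 with an estimated correlation), with CD79A at 0.20 (SE 0.06). Neutrophils rose in 3 of 8 (3 over the list alone; adjusted p = 0.338 with an estimated correlation), with the formyl peptide receptor gene FPR1 at 0.18 (SE 0.04). The respiratory chain was lower in 9 of 15 (10 over the list alone; adjusted p = 0.338 with an estimated correlation), with NDUFS1, a subunit of complex I, at -0.16 (SE 0.03) without and -0.12 (SE 0.02) with the index. WNT and beta-catenin targets were lower in 4 of 15 (5 over the list alone; adjusted p = 0.338 with an estimated correlation), with TBX3 at -0.20 (SE 0.04). The acute phase list was lower in 6 of 16 with 1 higher (7 and 1 over the list alone; adjusted p = 0.512 with an estimated correlation). Lipid and cholesterol synthesis was lower in 5 of 12 (5 over the list alone; adjusted p = 0.439 with an estimated correlation). With the index in the fit 4 respiratory chain genes and 2 of lipid and cholesterol synthesis were lower, lists whose scores fell with the index (r = -0.712 and -0.502). Then 4 WNT and beta-catenin targets and 6 acute phase genes were lower, and 10 stellate, 4 B and plasma cell, 4 neutrophil and 1 acute phase genes higher. Lower were also 8 genes of bile acid and xenobiotic transport, 16 of complement and coagulation and 14 of hepatocyte function. Without the index camera called neither macrophages (2 of 15 higher), T and NK cells (1 of 17 higher), endothelial cells (1 of 16 higher, 2 lower) nor red blood cells (0 of 7). It also called neither metallothioneins (0 of 7), NRF2 targets (3 of 12 lower), hypoxia and glycolysis (2 of 16 lower, 1 higher), interferon response (3 of 18 lower), nor antigen presentation (1 of 16 higher, 1 lower). Nor did it call early response and heat shock (3 of 15 higher), proliferation (1 of 18 lower), ribosomal proteins (0 of 16) nor oncofetal genes (2 of 15 higher). With the index, T and NK cells, antigen presentation and early response and heat shock were called higher as well, and none of these calls held (adjusted p = 0.548, 0.548 and 0.490 with an estimated correlation).

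AFP, the fetal albumin homologue, is the serum marker of aggressive hepatocellular carcinoma. ARID3A, a transcription factor, had a slope on AFP of 0.32 (SE 0.04, limma adjusted p = 1.0e-11, n = 99 and 33) and 0.31 (SE 0.04) with the index, and MEP1A, a metalloprotease, 0.33 (SE 0.04) and 0.34 (SE 0.05). GPC3, the oncofetal glypican, had 0.47 (SE 0.08) and 0.37 (SE 0.10), and H19, an imprinted RNA of fetal liver, 0.41 (SE 0.07) and 0.28 (SE 0.08). TYMS, thymidylate synthase, had 0.25 (SE 0.03) and 0.13 (SE 0.03), and SQLE, an enzyme of cholesterol synthesis, 0.28 (SE 0.05) and 0.27 (SE 0.05). Lower with AFP in both fits were SLC10A1, the bile acid importer of mature hepatocytes, at -0.21 (SE 0.07) and -0.42 (SE 0.07), and CYP2A6, a cytochrome P450, at -0.26 (SE 0.07) and -0.41 (SE 0.08).

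AFP itself had r = -0.528 with the index, the strongest of the 3 anchor genes. By limma 11405 of 16746 genes were associated with it, 6755 positively and 4650 negatively, against 496 with the index in the fit, 351 and 145, and 331 were called in both, 299 of them with the same sign. CHEK2, a checkpoint kinase, led the first fit with a slope of 0.31 (SE 0.03) and kept 0.16 (SE 0.03) with the index. It was followed by SLC35D2, PAQR9, IDI1, CBX5, TYMS, SNHG1, ARID3A, MBNL3 and HNRNPA0, all still past the threshold with the index. The negative side held RUNDC3B, at -0.32 (SE 0.04) and -0.21 (SE 0.04) with the index, then MATN4, PCAT18, FSHR, C12orf50, SOX7, HYAL6P, FILIP1, CCDC184 and LCA5L. Among these, FSHR, C12orf50, HYAL6P, CCDC184 and LCA5L did not pass with it. Across tumours CHEK2 and AFP had r = 0.646 and rho = 0.629 (permutation p = 1e-05 for each, adjusted p = 1.2e-05), 0.628 without the 2 tumours at the extremes, 0.652 in centre A and 0.643 in centre B, and a partial r of 0.441 given the index.

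With the index TRIM71, a stem cell regulator, had the strongest association, at 0.58 (SE 0.07, adjusted p = 2.4e-10) against 0.21 (SE 0.08) without it. After it came IGSF1, ARID3A, MEP1A, the phosphatase gene DUSP9 (0.60, SE 0.09), DLK1 (0.76, SE 0.12), the growth factor receptor gene FGFR4 (0.22, SE 0.04), NREP, HIC2 and DQX1. On the negative side were SLC10A1, PEX11G, RUNDC3B, CES2, CYP2C8, STARD5, BMERB1, CYP2A6, ACYP2 and FNDC5, between -0.42 and -0.13. Without the index IGSF1, HIC2, DQX1, PEX11G, CYP2C8, BMERB1 and FNDC5 did not pass, and the slopes of DQX1 (-0.00552) and PEX11G (0.00698) had the opposite sign. Several of these associations were weaker by rank, and DQX1 had rho = -0.277 over all tumours (permutation p = 0.00136, adjusted p = 0.00157) and a rank partial correlation of 0.0453 given the index. TRIM71 and AFP had r = 0.234 (permutation p = 0.00733, adjusted p = 0.00807) and rho = -0.0106 (permutation p = 0.905) over all tumours, 0.135 without the 2 at the extremes, 0.297 in centre A and -0.00442 in centre B. They had a partial r of 0.589 but a rank partial correlation of 0.211 given the index, and r = 0.606 with rho = 0.386 on the 99 arrays of lower index. For FGFR4 the values on those 99 arrays were r = 0.497 and rho = 0.478.

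The list of oncofetal genes was not called by camera in the first fit (8 of 14 higher and 1 lower, the same counts over the list alone; adjusted p = 0.594). With the index 9 were higher and 0 lower (adjusted p = 5.8e-14), and this held (adjusted p = 3.0e-09 with an estimated correlation), with IGF2BP3, an RNA-binding oncofetal protein, at 0.31 (SE 0.06). By rank given the index the partial correlations with AFP were 0.349 for GPC3 (0.313 by Pearson's r), 0.280 for H19, 0.154 for IGF2BP3, 0.101 for DLK1 and 0.0203 for SALL4, and -0.120 for IGF2, -0.0659 for PEG3 and -0.0606 for HMGA2. Proliferation went from 10 of 18 higher and 2 lower (adjusted p = 0.226) to 9 higher and 0 lower, which also held (adjusted p = 0.0146 with an estimated correlation), with CDK1 at 0.13 (SE 0.03) and AURKB at 0.22 (SE 0.05). Ribosomal proteins were higher in 12 of 16 (12 over the list alone; adjusted p = 0.00984, adjusted p = 0.994 with an estimated correlation) and the respiratory chain in 11 of 15 (11 over the list alone; adjusted p = 0.0399, adjusted p = 0.994 with an estimated correlation). Both are lists whose scores fell with the index, and with it in the fit 1 and 0 of their genes were higher. Lipid and cholesterol synthesis was higher in 7 of 12 (7 over the list alone; adjusted p = 0.118) and with the index in 2, when camera called it (adjusted p = 0.00197, adjusted p = 0.420 with an estimated correlation). Ribosomal proteins were called again (adjusted p = 0.00819, adjusted p = 0.445 with an estimated correlation). Camera with the index also called lower hepatocyte function (2 of 26 genes), interferon response (1 of 18), complement and coagulation (1 of 19), bile acid and xenobiotic transport (2 of 13), and macrophages (1 of 15). With 0 genes past the threshold it called the acute phase, antigen presentation, endothelial cells, metallothioneins, early response and WNT and beta-catenin lists lower. None of these lower calls held (adjusted p between 0.420 and 0.534 with an estimated correlation). The slopes of 0 genes differed between the centres in the first fit (2416 at an unadjusted p under 0.05) and of 1 gene, NLRP4, with the index (768 unadjusted).

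GLUL is the usual marker of beta-catenin activity in hepatocellular carcinoma, since its gene is a target of that pathway in perivenous hepatocytes. All 14 tested WNT and beta-catenin targets were higher with higher GLUL (14 adjusted over the list alone; camera adjusted p = 3.3e-26, adjusted p = 1.0e-06 with an estimated correlation). RHBG, an ammonium transporter, had a slope of 0.85 (SE 0.06, limma adjusted p = 1.1e-23, n = 99 and 33), NKD1 0.71 (SE 0.07), NOTUM 0.78 (SE 0.08) and LGR5, a receptor of R-spondins, 0.84 (SE 0.09). Genes of T and NK cells were lower with higher GLUL, in 13 of 17 (14 over the list alone; adjusted p = 2.0e-06, adjusted p = 0.445 with an estimated correlation), among them CD6 at -0.27 (SE 0.05), CD3G, a subunit of the T cell receptor complex, at -0.34 (SE 0.08), and KLRB1 at -0.25 (SE 0.06). The index had r = 0.252 with GLUL and r = -0.138 with the T and NK score, and with it in the fit 14 of 14 and 13 of 17 passed again (adjusted p = 0.273 with an estimated correlation for the latter).

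Over all genes 3675 were associated with GLUL, 1621 positively and 2054 negatively, and 2114 with the index, 1234 of them in both. Also named were the potassium channel gene KCNU1 at 0.96 (SE 0.08), SLC22A11, an organic anion transporter, at 1.11 (SE 0.10), ODAM at 0.97 (SE 0.09), RGSL2, ZNF648 and SLC13A3. With the index TBX3 and FBXO31 were added. On the negative side were HAL, histidase, at -0.62 (SE 0.08), ERICH5 at -0.57 (SE 0.08), SLPI, a secreted protease inhibitor, at -0.70 (SE 0.11), and HPGD, which degrades prostaglandins, at -0.53 (SE 0.08). They were joined by ELOVL7, TNFAIP8, TMSB4XP8, TCF7L1, VEGFB and FURIN, with PARVG added by the index. RHBG and GLUL had r = 0.762 and rho = 0.747 (permutation p = 1e-05 for each, adjusted p = 1.2e-05), 0.772 without the 2 tumours at the extremes, 0.825 in centre A and 0.622 in centre B. Slopes of 0 genes differed between the centres (573 at an unadjusted p under 0.05).

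Stellate cells and fibroblasts fell with higher GLUL in 12 of 19 (15 over the list alone; adjusted p = 0.445 with an estimated correlation) but in 4 of 19 with the index. Macrophages fell in 7 of 15 (7 over the list alone), with FCER1G at -0.21 (SE 0.04). Neutrophils fell in 4 of 8 (5 over the list alone), and B and plasma cells in 3 of 11 (3 over the list alone), with CD38 at -0.27 (SE 0.06) (adjusted p = 0.445, 0.445 and 0.542 with an estimated correlation). Camera called neither endothelial cells (1 of 16 lower; adjusted p = 0.0922) nor red blood cells (0 of 7; adjusted p = 0.784). Antigen presentation was lower in 7 of 16 (8 over the list alone; adjusted p = 0.445 with an estimated correlation), with HLA-DPA1 at -0.23 (SE 0.05). The acute phase list was lower in 7 of 16 (7 over the list alone; adjusted p = 0.498 with an estimated correlation), with CRP, C-reactive protein, at -0.46 (SE 0.08). Early response and heat shock was lower in 5 of 15 (6 over the list alone; adjusted p = 0.445 with an estimated correlation), with IER3 at -0.33 (SE 0.06). Ribosomal proteins were lower in 7 of 16 (9 over the list alone; adjusted p = 0.445 with an estimated correlation). With the index in the fit 3 antigen presentation and 2 ribosomal protein genes were lower, lists whose scores fell with the index (r = -0.501 and -0.710). Then 6 macrophage, 4 neutrophil, 3 B and plasma cell, 4 acute phase and 4 early response genes were lower, and 1 acute phase gene higher. Higher with GLUL were 3 of 13 genes of bile acid and xenobiotic transport (3 over the list alone; adjusted p = 0.542 with an estimated correlation), SLCO1B3 at 0.43 (SE 0.07) and CYP8B1 at 0.40 (SE 0.09) among them, and 6 with the index. With the index camera also called lipid and cholesterol synthesis and NRF2 targets higher, each in 4 of 12 (adjusted p = 0.0147 and 0.0226, adjusted p = 0.365 and 0.446 with an estimated correlation). Of the 11 lists called by camera with GLUL, only the WNT and beta-catenin targets held with an estimated correlation, in both fits.

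Results for GLUL depended on the probe. Its other kept probes had r = 0.456 and 0.512 with the chosen probe, and r = -0.477 and -0.453 with the index against 0.252. Used as the anchor they called 11728 and 11322 genes, and of the 2422 and 2291 shared with the chosen probe only 428 and 505 had the same sign. With the index they called 2773 and 2171 genes, with 773 of 807 and 827 of 835 shared genes of the same sign. The WNT and beta-catenin targets were then higher in 13 and 12 of 14 (adjusted p = 3.9e-07 and 9.7e-09 with an estimated correlation), against 13 and 14 without it (adjusted p = 0.228 and 0.0494 with an estimated correlation). T and NK genes were lower in 6 and 8 of 17 with the index (camera adjusted p = 3.0e-06 and 2.8e-06, adjusted p = 0.498 and 0.375 with an estimated correlation). Without it 7 were lower and 1 higher with the former probe and 6 lower with the latter, and camera did not call them (adjusted p = 0.0987 and 0.0787).

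**Figure D2:**
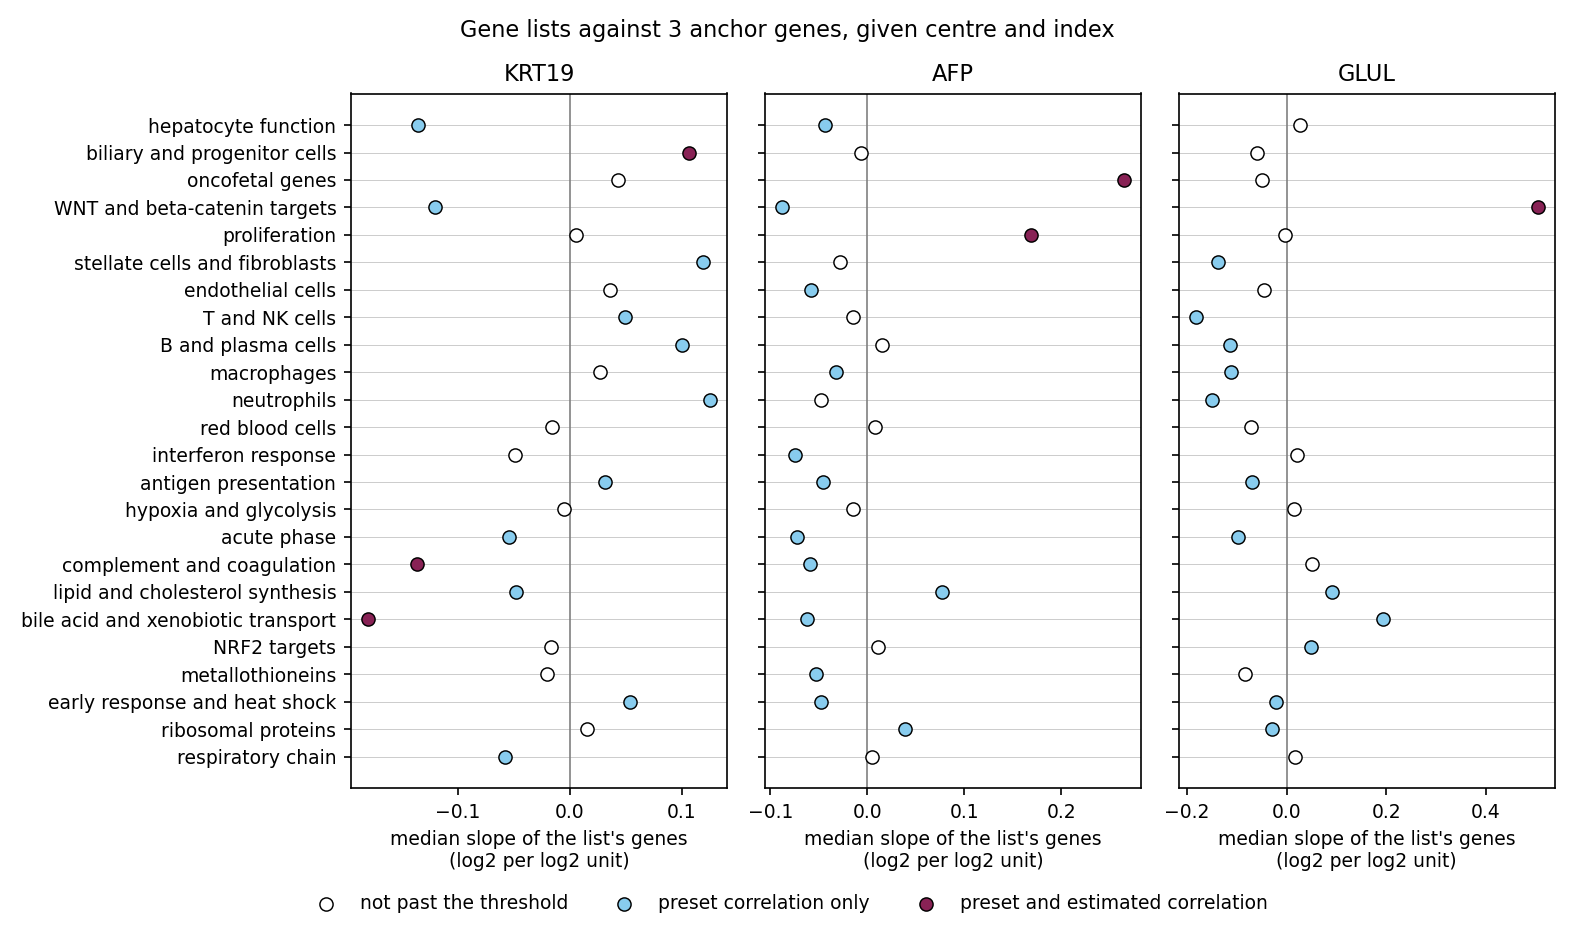
Median slope of each list's genes on KRT19, AFP and GLUL (log2 per log2 unit of the anchor gene), with the centre and the nonspecific signal index in the fit, and marks for lists called by camera at its preset and with an estimated correlation. The median slope of the WNT and beta-catenin targets on GLUL was 0.50, that of the oncofetal genes on AFP 0.26, and that of bile acid and xenobiotic transport on KRT19 -0.18.

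Pairs of genes and of list scores were related as fixed before the data were examined. Of 24 pairs, 19 passed after adjustment over the family of 24, 16 of them positive and 3 negative, 16 passed by rank, and 19 passed given the index. KRT19 and EPCAM had r = 0.378 and rho = 0.368 (permutation p = 6.0e-05 for each, adjusted p = 9.6e-05 and 0.000111), 0.384 without the 2 extreme tumours, 0.402 in centre A and 0.3001 in centre B. AFP and GPC3 had r = 0.444 and rho = 0.459 (permutation p = 1e-05 for each, adjusted p = 2.2e-05), 0.456 without the extremes, 0.420 in centre A and 0.512 in centre B. GLUL and AXIN2, a feedback target of the pathway, had r = 0.511 and rho = 0.544 (permutation p = 1e-05 for each, adjusted p = 2.2e-05), 0.507 without the extremes, 0.517 in centre A and 0.475 in centre B. The oncofetal pair of AFP and IGF2BP3 had r = 0.367 (permutation p = 7.0e-05, adjusted p = 0.000105) but rho = 0.0827 (permutation p = 0.346, adjusted p = 0.378), 0.283 without the extremes, 0.414 in centre A and 0.174 in centre B, with a partial r of 0.441 given the index. AFP and DLK1 had r = 0.214 (permutation p = 0.0138, adjusted p = 0.0184) and rho = -0.0741 (permutation p = 0.399, adjusted p = 0.416), with r = 0.0692 without the 2 extreme tumours. Given the index their partial r was 0.471 (adjusted p = 1.7e-05), and without the 33 arrays of highest index r was 0.559 (adjusted p = 2.2e-05).

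AFP and EPCAM had r = 0.441 and rho = 0.346 (permutation p = 1e-05 and 5.0e-05), 0.387 without the extremes, 0.378 in centre A and 0.642 in centre B. GLUL and LGR5 had r = 0.633 and rho = 0.657 (permutation p = 1e-05 for each), 0.627 without the extremes, 0.639 in centre A and 0.612 in centre B. GLUL and TBX3 had r = 0.404 and rho = 0.274 (permutation p = 1e-05 and 0.00165), 0.388 without the extremes, 0.458 in centre A and 0.281 in centre B, with a partial r of 0.684 given the index. KRT19 with SOX9 (r = 0.165, adjusted p = 0.0702), with KRT7 (r = 0.154, adjusted p = 0.0891) and with AFP (r = -0.0290, adjusted p = 0.740) did not pass, while the pairs with SOX9 and KRT7 passed given the index, at partial r of 0.237 and 0.248.

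Among list scores, proliferation was lower where hepatocyte function was higher (r = -0.403, rho = -0.547, permutation p = 4.0e-05 and 1e-05, adjusted p = 7.4e-05 and 2.2e-05; -0.436 without the extremes, -0.363 in centre A and -0.531 in centre B). It was higher with oncofetal genes (r = 0.498, rho = 0.431, permutation p = 1e-05 for each, adjusted p = 2.2e-05; 0.364 without the extremes, 0.480 and 0.631 by centre). Biliary and progenitor cells went against hepatocyte function (r = -0.377, rho = -0.424, permutation p = 2.0e-05 and 1e-05; -0.350 without the extremes, -0.377 and -0.339 by centre) and with stellate cells and fibroblasts (r = 0.553, rho = 0.569, permutation p = 1e-05 for each; 0.562 without the extremes, 0.491 and 0.678 by centre). Their correlations with proliferation (r = 0.107) and with oncofetal genes (r = 0.0804) did not pass. Scores of T and NK cells rose with those of macrophages (r = 0.567, rho = 0.581; 0.539 without the extremes, 0.518 and 0.713 by centre) and antigen presentation (r = 0.538, rho = 0.572; 0.483 without the extremes, 0.428 and 0.809 by centre). Those of stellate cells and fibroblasts rose with endothelial cells (r = 0.668, rho = 0.681; 0.650 without the extremes, 0.710 and 0.499 by centre), all with permutation p = 1e-05.

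WNT and beta-catenin targets and T and NK cells had r = -0.228 (permutation p = 0.00856, adjusted p = 0.0121) and rho = -0.119 (permutation p = 0.175, adjusted p = 0.222), -0.225 without the extremes, -0.268 in centre A and -0.0958 in centre B, with a partial r of -0.240 given the index. T and NK cells with interferon response had r = 0.196 (permutation p = 0.0244, adjusted p = 0.0308) and rho = 0.276 (permutation p = 0.00129), 0.0932 in centre A and 0.475 in centre B. By Pearson's r, T and NK cells with interferon response did not pass given the index (0.167, adjusted p = 0.0666) nor without the 2 extreme tumours (0.158, adjusted p = 0.0984). Hypoxia and glycolysis with hepatocyte function had r = 0.354 and rho = 0.329 (permutation p = 6.0e-05 and 0.000110), 0.337 without the extremes, 0.471 in centre A and 0.0924 in centre B. They did not pass given the index (0.165, adjusted p = 0.0666), with which both scores fell. The acute phase and hepatocyte function had r = 0.755 and rho = 0.607 (permutation p = 1e-05 for each), 0.651 without the extremes, 0.784 in centre A and 0.7502 in centre B. No pair's correlation differed between the centres after adjustment (0 of 24 by permutation, 2 at an unadjusted p under 0.05).

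**Figure D3:**
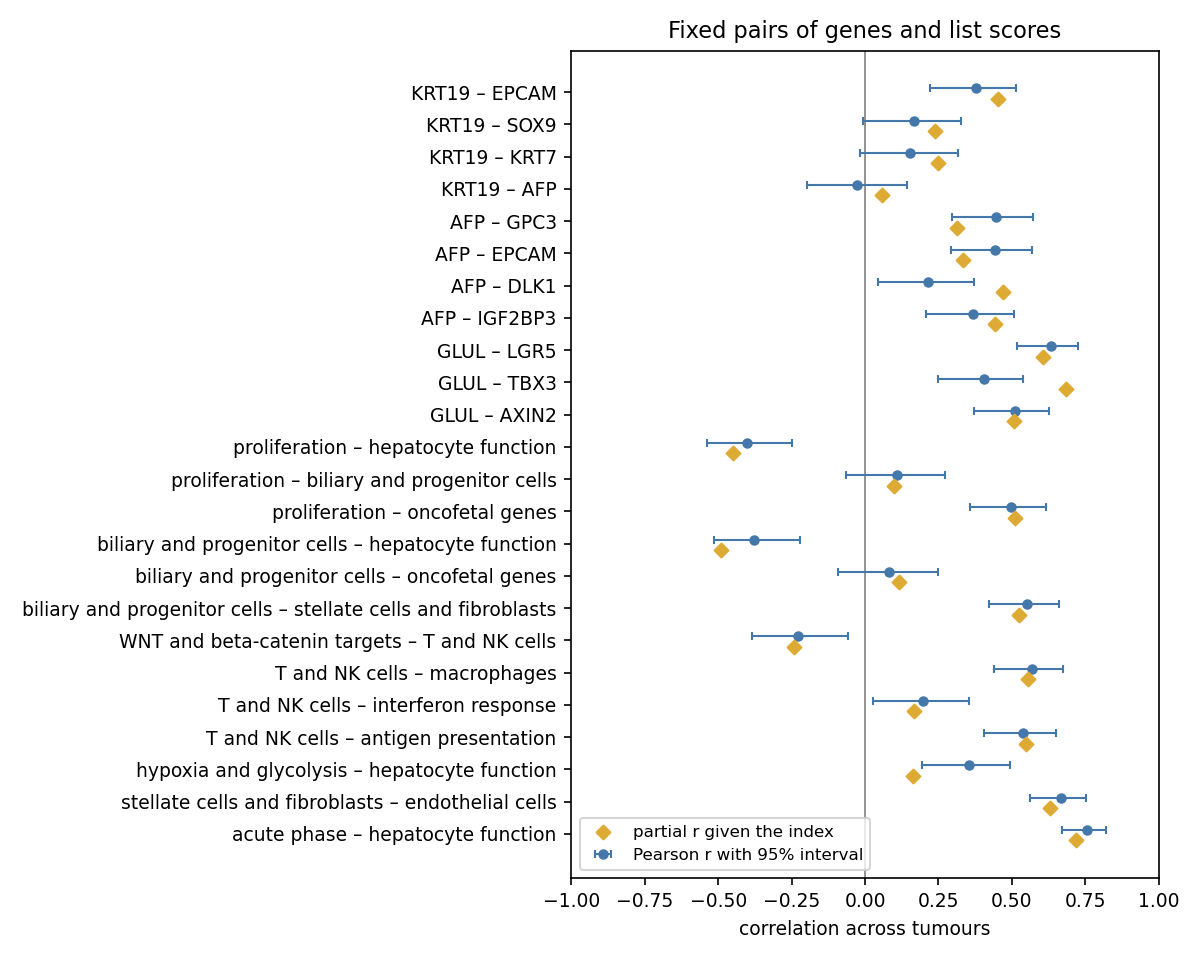
Pearson correlation across tumours of both centres for the 24 fixed pairs of genes and list scores, with 95% intervals, and the partial correlation given the nonspecific signal index. The correlation of acute phase with hepatocyte function was 0.755, and that of GLUL with TBX3 0.404, against 0.684 given the index.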

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

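Tests of the nonspecific signal index, of the order of listing, of other splits of the tumours, and of the partial correlation of GLUL with T and NK cells given the index were chosen only after the result was seen; the random removals, the tumours with conflicting labels and the test against other non-tumour scores were planned before theirs was.

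A gene's slope on AFP differed between the centres for NLRP4, by 0.49 (SE 0.10, limma adjusted p = 0.0311 with the index as a covariate), with a slope of -0.04 in centre A (n = 99) and 0.45 in centre B (n = 33); it was picked out by the interaction test over 16746 genes, and chosen after its value was seen. AFP and DLK1 were picked out because their correlation was 0.350 in centre A and -0.375 in centre B (permutation p of the difference = 0.0435), which failed the adjustment over 24 pairs (adjusted p = 0.464). T and NK cells with antigen presentation were picked out because r was 0.428 in centre A and 0.809 in centre B (permutation p of the difference = 0.0070), which also failed the adjustment (adjusted p = 0.168).

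The difference between the centres, 2796 genes by limma, was not reached by chance splits: among 100 splits of the tumours into 99 and 33 only 1, the real one, gave as many genes, and the highest other gave 3. Such splits scatter the 20 tumours listed later in centre B, so they cannot tell the centre from a batch of arrays. The index was higher in centre B, and with it in the fit 25.02% of the 1355 genes higher in centre B kept at least 50% of their log2 difference, as did 47.6% of the 1441 lower genes, with median ratios of 0.236 and 0.486. The index may thus account for part of either side, and where neither bound was passed its share cannot be told apart from that of the centres, which differ in the index themselves. For the 497 genes called the same way with and without the index, labels were exchanged among tumours of similar index. Only 1 of 100 such splits, the real one, gave as many (highest other 7, mean index difference of the splits 0.473 against 0.488). An index difference of this size therefore did not by itself give such a count. The 497 were picked by passing with the index, so the splits cannot exclude nonspecific signal that the index does not capture. The olfactory receptor gene OR2G2 is among them. An array batch also stays open and untested, and the labels give no name for it. The index break along the listing of centre B (13 and 20 tumours) may be a trace of it. Handling, case mix and treatment at the centres stay open and untested too. The drop to 91 genes without the 33 arrays of highest index says nothing about the index. Of 100 random removals of as many arrays per centre, 52 gave as few (median 88, range 2 to 5795). All 5 tumours with conflicting labels were labelled centre A but had the title prefix of centre B, and 2 lay nearer to centre B. By that measure 84.04% of the 94 other centre A tumours and 66.7% of the 33 centre B tumours lay on their own side. The 5 had indices of 8.11, 7.67, 8.78, 9.18 and 6.48, against means of 7.11 in centre A and 8.18 in the later part of centre B. Other arrays of centre A reached 9.33, so neither measure settles single tumours, and wrong labels stay open for those 5.

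Genes associated with AFP, 11405 by limma, depended on the index: 10.3% kept at least 50% of their slope with the index in the fit, and the median ratio of slopes was 0.0675. The fall to 496 genes with the index had been seen before, and AFP itself moved with the index (r = -0.528), so this share supports no explanation. Nonspecific signal and a relation to AFP cannot be told apart for these genes, because AFP and the index vary together. The 299 genes called with the same sign in both fits stay open to a biological reading, for which no group of the design offers a test.

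T and NK cell genes were lower with higher GLUL also after correction for the centre and the index, with a partial correlation of -0.332 (95% interval -0.477 to -0.170, n = 99 and 33). The fit with the index had already shown 13 of 17 of these genes lower. This value therefore restates that result and is no separate test of nonspecific signal. Given also the scores of stellate, endothelial and macrophage genes it was -0.225 (95% interval -0.384 to -0.0529). Scores of marker genes take out non-tumour tissue only in part, so this remainder cannot exclude an equal loss of every kind of it. These partial correlations used the chosen GLUL probe only. Macrophage (-0.282), B and plasma cell (-0.261) and stellate (-0.244) scores also fell with GLUL given the centre and the index, while for endothelial cells the interval held 0 (-0.137, 95% interval -0.302 to 0.0359). A smaller share of non-tumour cells therefore stays open as an explanation. The list's call was lost with an estimated correlation, and no biological explanation was tested, because the design names no group for it.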

How the results depend on the processing

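Settings with the index, without the arrays of highest index, with other GLUL probes, or with neqc on the lowest probes were chosen after the data were seen; the others were planned. How far signal over background limits them was not compared with other limits. Over the alternatives, 299 of 332 centre differences of named genes kept direction and call, 32 were no longer past the threshold and 1 reversed. These losses all came from the settings that concern the index. With the index as a covariate 12 differences kept their call and 12 did not. Without the arrays of highest index 3 kept it, 20 did not and 1 reversed. Of 1030 slopes 986 kept direction and call, 42 were no longer past the threshold and 2 reversed. Of 428 list calls these were 369, 48 and 11, and of 335 correlations 304, 18 and 4, with 9 newly past. The main counts stayed within 1.5 times in 71 of 98 cases. Outside it, genes that differed between the centres numbered 5695 with detected probes as a covariate, 10101 with array weights, 5902 by title prefix, 5037 with the hepatocyte score, 316 with a log2 difference of at least 1 (97.8% higher, against 48.5%), 1471 with the index (67.3% higher) and 91 without the arrays of highest index. Lists numbered 2 with detected probes, 2 without arrays of few detected probes, 4 with the index and 9 without the arrays of highest index. For KRT19 the counts were 1487 without those arrays, 1700 in centre A and 99 in centre B, for AFP 496 with the index and 806 without those arrays. For GLUL they were 6125 by the mean of probes, 2136 with detected probes, 2232 with array weights, 2114 with the index, 1521 without those arrays, 1972 in centre A, 34 in centre B, 11728 and 11322 by other probes, and 2171 by the latter with the index. In centre B alone 11 pairs passed. The cause was not tested.

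Reversals were MAGEA10 between the centres, at -0.22 without the arrays of highest index, and TMSB4XP8, at slopes of 0.17 and 0.0876 on other GLUL probes. Lists that reversed on GLUL, with camera adjusted p, were ribosomal proteins with the mean of probes (0.297), with one other probe (0.0753; 0.551 with the index) and the other (0.0390; 0.391 with the index); antigen presentation (0.281, 0.815 with the index, and 0.619); acute phase (0.766); and early response (0.504 and 0.862). Correlations that reversed were KRT19 with KRT7 (-0.234) and AFP with DLK1 (-0.375) in centre B, and KRT19 with AFP given the index (0.0567) and without the arrays of highest index (0.0418). The cause was not tested.

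No paired analysis was possible because replicate numbers were given in accession order and only name a tumour. A slide block was not run, as columns and labels give no slide, neqc as planned lacked detection p-values, and KRT19 and AFP have no other kept probe.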

Other observations

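The list of NF-kB genes and of glucocorticoid-induced genes, and the test with the hepatocyte score, were fixed before their results were seen, but all of them were chosen only after FKBP5, TSC22D3 and TAT had been seen among the genes higher in centre B.

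Genes induced by glucocorticoid hormones were higher in centre B with the index as a covariate. Of 14 tested genes not seen before, 6 were higher by limma and 0 lower, and 12 had a positive difference: ZBTB16, a transcription factor, at 0.88 (SE 0.23), PDK4, a kinase that spares glucose, at 0.77 (SE 0.16), ERRFI1 at 0.70 (SE 0.15), DDIT4, an inhibitor of mTOR signalling, at 0.68 (SE 0.17), CEBPD at 0.37 (SE 0.12) and KLF9 at 0.34 (SE 0.09). SGK1, at 0.27 (SE 0.16), and PER1, at 0.11 (SE 0.09), did not pass. Without the index the differences were 0.84 for ZBTB16, 0.44 for PDK4, 0.50 for ERRFI1, 0.41 for DDIT4, 0.16 for CEBPD and 0.01 for KLF9. For SGK1 and PER1 they were 0.05 and -0.12. The median difference of the list was 0.26 with the index, 0.17 without it, and 0.08 without the arrays of highest index.

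As a hypothesis, the tumours of the centres may differ in glucocorticoid exposure around the removal of the liver. The list was higher in centre B by camera with the index (unadjusted p = 0.000101, p = 0.0197 with an estimated correlation), with a median log2 difference of 0.26, as the hypothesis predicts. Lists not chosen for it had medians of similar size with the index: 0.24 for the respiratory chain, 0.30 for hepatocyte function and 0.30 for bile acid and xenobiotic transport. Others were below 0, such as biliary and progenitor cells (-0.19). A median of this size is thus not particular to the glucocorticoid list. With the hepatocyte score in the fit too, the median was 0.19 (camera p = 0.000564, p = 0.0350 with an estimated correlation). That score takes out hepatocyte content only in part, and it holds TAT, one of the genes that prompted the hypothesis. More hepatocytes in the tumours of centre B therefore cannot be excluded as the cause. A list of NF-kB targets, which glucocorticoids restrain, had a median difference of -0.14 with the index, -0.38 without it and -0.25 without the arrays of highest index, with 2 of 15 genes lower, CXCL3 (-0.50, SE 0.16) and NFKB2 (-0.38, SE 0.12), and 1 higher, NFKBIA (0.16, SE 0.05); camera gave p = 0.00461 but p = 0.110 with an estimated correlation, so this list leaves the hypothesis open. Other differences in handling or in array batch between the centres were not tested.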
